A study of Delphinapterus leucas with 24 samples.

How the data were processed

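Blood of beluga whales (Delphinapterus leucas) sampled in Bristol Bay, Alaska, was profiled by RNA sequencing in 24 libraries, 8 from each of the years 2012, 2013 and 2014. Per the labels' protocols, whole blood RNA was extracted with a PAXgene kit, which stabilises RNA at collection, and strand-directional libraries were made with a NEBNext Ultra kit. Reads were handled with Trimmomatic, Bowtie2 and RSEM 1.2.21, per the submitters' processing notes, which give no role or order for these tools. The series' design text says that the transcriptome was assembled from the reads themselves with Trinity, so that a measured feature is an assembled transcript group and not a gene of a genome annotation. The deposited values are read here as TPM (transcripts per 1000000, as RSEM writes them), because each column sums to between 987069 and 997966 and the column values are not whole. The sequencing run, the read length and the assembly settings are not given in the sources used here.

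The deposited table lists 45872 features. The values show that it had been filtered, since the lowest mean over the libraries was 0.995 TPM and every listed feature was above 0 in at least 12 libraries. A feature present only in the 9 female libraries could therefore not be listed, whereas one present only in the 15 male libraries could. Of the features, 18019 carry a protein accession and 14080 carry an Entrez Gene ID, with 9856 distinct IDs. The files do not pair these IDs with gene symbols and no symbol table was used here, so features are named by their assembly identifier and Entrez Gene ID, at most 2 per direction and comparison. The gene lists and blood cell markers fixed beforehand (immune response, metabolic, stress, blood cell type, sex chromosome and mitochondrial lists) are written as symbols and were not analysed here. The globin and mitochondrial shares as defined by symbol were not computed either, nor were the fits that use a neutrophil or erythroid list. Whether the most abundant features, whose share was analysed, belong to any of these lists was not looked up.

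TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval or detection floor is given. An exact 0 is reported as listed at 0. TPM sums to a fixed total, so a library in which a few features take more of the total lists lower values for the rest.

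Sex, year and sampling date were taken from the labels. The groups held 3 females and 5 males in 2012, 4 females and 4 males in 2013, and 2 females and 6 males in 2014. Library numbers in the labels differ within a year, and whether an animal was sampled again in another year is not given in the sources used here. p-values measure the spread between these libraries. The highest Spearman correlation between a pair of libraries was 0.900 and the lowest 0.719, so no library was counted as a copy of another.

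Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear models with empirical Bayes variances, trend and robust options) over the 45832 features at 1 TPM or more in at least 8 libraries. The sex comparison used all 24 libraries with year in the model, and the year comparisons used all 24 with sex in the model, as an F test over both year terms and as 3 pairwise contrasts. The interaction of sex and year was an F test over both interaction terms. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are on the log2(TPM + 1) scale, which understates the change of low features. The design had been fixed for either counts or normalised values before the data were examined, and the table called for the second.

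Features named in the text have the smallest adjusted p among calls with an Entrez Gene ID, 2 per direction. The rule fixed beforehand asked for gene symbols and could not be applied, so this rule was chosen after the values were seen, as were the unannotated features named as lower in males. Library measures were compared with exact permutation tests (scipy 1.17.1) and, for the F ratio among years, with 100000 permutations, all adjusted together over 25 tests. Those on means were two-sided.

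Alternatives fixed before the data were examined were median-ratio scaling of the TPM (libraries divided by the median ratio to the geometric mean of the libraries over features above 0 in every library), quantile normalisation, limma without trend, no low value filter, a filter at 5 TPM, a pseudocount of 0.1, models without the other factor, library weights, day of the year as a covariate, male libraries only, and each library left out. Chosen after seeing the data were leaving out the 3 most abundant features, their log2 share as a covariate, leaving out the 2 libraries with over 50% of TPM in those features, sampling date as a block in the sex comparison (with and without scaling), and median-ratio scaling combined with day of the year, with male libraries only and without those 2 libraries.

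The fit was tested on simulated data with the means and residual spread of the 45832 features, independent between features, and 200 features changed per comparison. The changed features were drawn only from those with a mean log2(TPM + 1) of 2 or more, so the shares below do not cover lower features. For the sex comparison 10.4% of the features changed by 0.5 log2 units were called, 71.6% of those changed by 1 and 98.5% of those changed by 2, with 7 false calls. For 2014 minus 2012 these shares were 1.49%, 65.7% and 95.5%, with 2 false calls. The simulation held no shift shared by the features of a library.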

Results

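RNA was measured in the blood of beluga whales, an Arctic toothed whale, to find transcripts that varied between the sexes or among 3 years of sampling. The 24 libraries were 9 labelled female and 15 labelled male, with 8 libraries per year. Sampling ran from 1 to 12 September in 2012, from 23 to 30 August in 2013, and from 25 August to 3 September in 2014. The depth of the libraries is unknown because TPM does not keep it.

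The libraries differed widely in how much of the TPM total a few features took. The most abundant feature, TR28281|c0_g1 (Entrez Gene ID 3043), averaged 137115 TPM and ranged from 13212 to 327269 between libraries. The next in abundance were TR7616|c0_g1 and TR7616|c0_g2, which both carry Entrez Gene ID 3040 and averaged 62725 and 55947 TPM. Together these 3 features held between 2.70% and 54.2% of the TPM of a library. Their share was 16.7% ± 15.8 (SD, n = 8) in 2012, 26.0% ± 14.8 (SD, n = 8) in 2013 and 34.1% ± 11.6 (SD, n = 8) in 2014. The rise of 17.3 percentage points from 2012 to 2014 had an exact permutation p = 0.0267 and an adjusted p of 0.0955 over the 25 tests of library measures, so it did not pass the correction. The shares of females and males, 28.4% ± 16.1 (SD, n = 9) and 23.9% ± 15.2 (SD, n = 15), differed by less than their spread (exact permutation p = 0.4998).

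**Figure D1:**
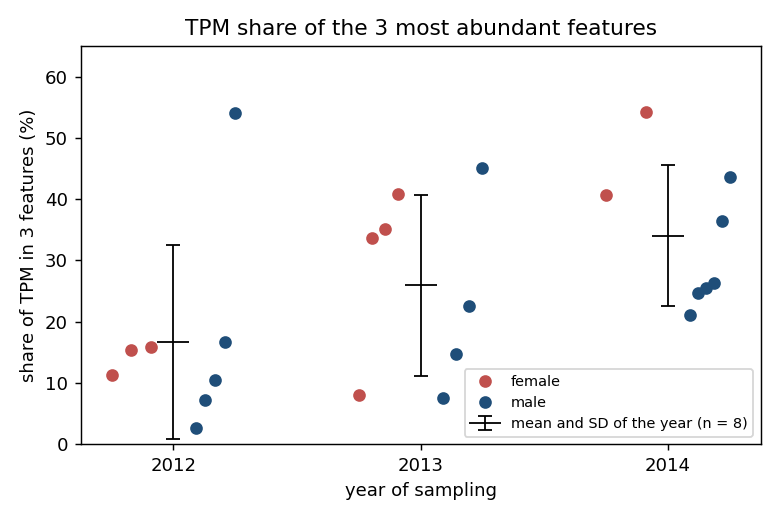
Share of the TPM total (%) held by the 3 most abundant features in each library (points, coloured by sex), by year of sampling, with the mean and SD of the 8 libraries of each year. The means were 16.7% in 2012, 26.0% in 2013 and 34.1% in 2014, and 1 male library of 2012 reached 54.1%.

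The median feature showed the opposite order. The median TPM of a library was 3.59 ± 0.993 (SD, n = 8) in 2012, 3.18 ± 0.769 (SD, n = 8) in 2013 and 2.35 ± 0.524 (SD, n = 8) in 2014. The difference between 2014 and 2012 was -1.24 TPM (exact permutation p = 0.00948, adjusted p = 0.0790), and that between 2014 and 2013 was -0.829 TPM (exact permutation p = 0.0253, adjusted p = 0.0955). The TPM total of the listed features was higher by 2304 in 2014 than in 2012 and by 2890 than in 2013, each with an adjusted p of 0.0622 (exact permutation p = 0.00497 and 0.00249). None of the 25 comparisons passed the correction, and the smallest adjusted p was 0.0622. The top 10 features held 9.49% to 61.6% of the TPM of a library, and between 295 and 973 features of a library were listed at 0.

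The comparison of the sexes asked which transcripts differed between males and females in any year. Most features that differed were present in males and near 0 in females. TR27873|c0_g1 (Entrez Gene ID 7317) lay between 41.7 and 161 TPM in the 15 males and at 0.2 TPM or less in the 9 females, of which 6 listed it at 0. TR5496|c0_g1 (Entrez Gene ID 8284) lay between 10.6 and 52.4 TPM in males and at 0.06 TPM or less in females. TR3799|c0_g3, which carries no annotation, showed the reverse, with 28.6 to 98.4 TPM in females and 0.01 to 0.08 TPM in males. TR1727|c0_g1, also without annotation, was at 5.81 ± 2.41 TPM (SD, n = 9) in females and between 0 and 3.0 TPM in males, 3 of which listed it at 0.

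Of 45832 features tested, 64 were called, 61 of them higher in males and 3 lower. The male minus female difference was 6.33 ± 0.19 (SE) for TR27873|c0_g1, with an adjusted p of 4.88e-33 in limma, and 4.86 ± 0.19 (SE) for TR5496|c0_g1, with an adjusted p of 1.56e-27. It was -5.81 ± 0.18 (SE) for TR3799|c0_g3 (adjusted p = 5.93e-32) and -1.68 ± 0.20 (SE) for TR1727|c0_g1 (adjusted p = 3.52e-08). Among the male-higher features, 54 had a female mean under 0.5 TPM and 20 were listed at 0 in all 9 females. The male means of those 54 ran from 1.67 to 87.0 TPM with a median of 7.77 TPM. In 55 features every male lay above every female, and in 1 feature every female lay above every male. Chance gives such a separation in one direction in a share of 7.65e-07 of features. An accession was carried by 35 of the 61 male-higher features and an Entrez Gene ID by 19. These 19 carried 12 distinct IDs, of which 7 were shared by at least 2 of the features.

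**Figure D2:**
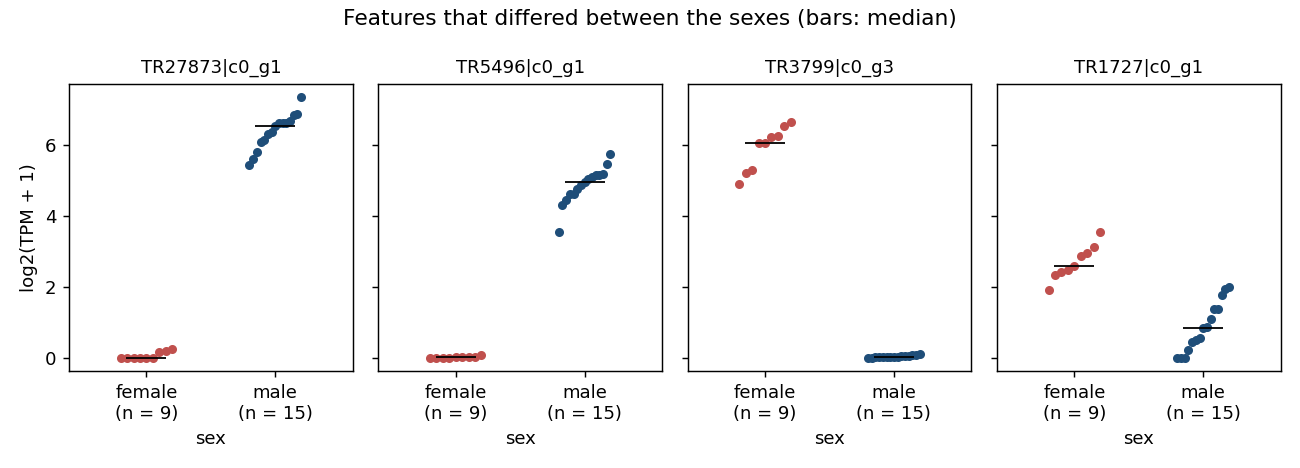
Level, as log2(TPM + 1), of 4 features in each of the 9 female and 15 male libraries (points), with the median of each sex as a bar. TR27873|c0_g1 and TR5496|c0_g1 were near 0 in every female, TR3799|c0_g3 was near 0 in every male, and TR1727|c0_g1 was lower in males, where it reached 3.0 TPM.

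Median-ratio scaling gave 78 calls with another split, 60 higher and 18 lower in males, and shared 60 of the male-higher and all 3 of the female-higher features with the deposited scale. All 4 of these named features kept their direction and passed the threshold on both scales.

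The comparison of years asked which transcripts varied between sampling seasons. In 2014 most features were listed lower than in 2012, with a median difference of -0.42 over all features tested, and 7887 were called, 7812 lower and 75 higher in 2014. TR18980|c1_g9 (Entrez Gene ID 7586) was at 3.83 ± 2.12 TPM in 2014 and 11.3 ± 4.95 TPM in 2012 (SD, n = 8 each), a difference of -1.35 ± 0.24 (SE, adjusted p = 0.0168 in limma). TR40286|c0_g1 (Entrez Gene ID 6431) was at 10.2 ± 2.71 TPM in 2014 and 25.2 ± 7.62 TPM in 2012 (SD, n = 8 each), a difference of -1.21 ± 0.22 (SE, adjusted p = 0.0168). TR34066|c0_g2 (Entrez Gene ID 6622) was at 32.4 ± 14.9 TPM in 2014 and 9.05 ± 6.09 TPM in 2012 (SD, n = 8 each), a difference of 1.81 ± 0.35 (SE, adjusted p = 0.0214). TR26870|c0_g2 (Entrez Gene ID 4635) was at 24.8 ± 7.26 TPM in 2014 and 12.3 ± 8.88 TPM in 2012 (SD, n = 8 each), a difference of 1.15 ± 0.25 (SE, adjusted p = 0.0214).

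The direction and the number of these calls depended on the scale. Median-ratio scaling, which brings such a median near 0 by construction, moved the median difference from -0.42 to -0.01. It left 241 calls, 181 higher and 60 lower in 2014. Of the 7812 lower features 60 were also called lower after scaling, and of the 75 higher features 10 were also called higher. Relative to that shift, TR18980|c1_g9 and TR40286|c0_g1 differed by -0.88 and -0.70 (adjusted p = 0.0426 and 0.0497 in limma). TR34066|c0_g2 and TR26870|c0_g2 differed by 2.29 and 1.64 and no longer passed (adjusted p = 0.0519 and 0.0708). On the deposited scale, leaving out male 2012 replicate 5 left 0 calls, male 2012 replicate 2 left 4 and female 2014 replicate 1 left 6, whereas leaving out male 2012 replicate 1 gave 31583. After scaling, leaving out male 2012 replicate 2 left 4 calls and leaving out male 2012 replicate 1 gave 1810. With day of the year in the model 0 features were called, and with the 3 most abundant features left out 6 were called.

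**Figure D3:**
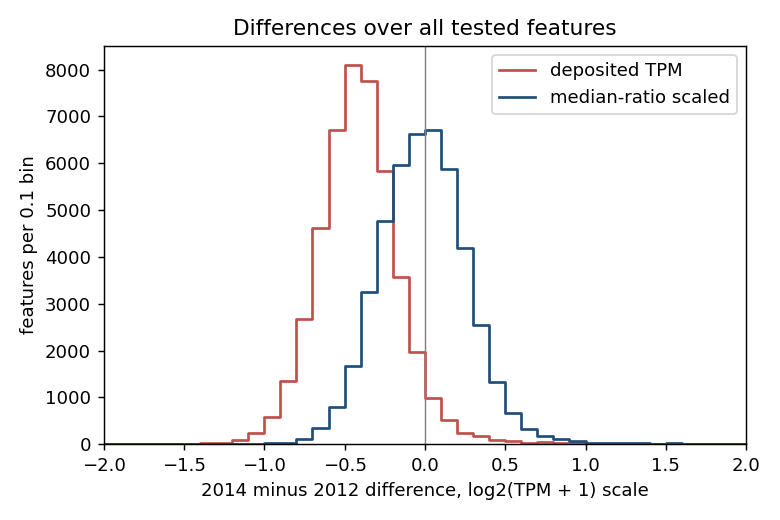
Number of features per 0.1-wide bin of the 2014 minus 2012 difference on the log2(TPM + 1) scale, over the 45832 features tested, for the deposited TPM and after median-ratio scaling. The median lay at -0.42 on the deposited scale and at -0.01 after scaling, which brings it near 0 by construction.

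No feature was called between 2013 and 2012 in limma (0 on the deposited scale and 0 after scaling), with 712 features at an unadjusted p under 0.05 and a median difference of -0.11. No feature was called between 2014 and 2013 (0 on both scales), with 11354 features at an unadjusted p under 0.05, a median difference of -0.31 and a smallest adjusted p of 0.0533. The number of calls for 2014 minus 2013 was 14205 with day of the year in the model and 11520 with library weights. It was 7100 without male 2012 replicate 1 and 3070 without female 2013 replicate 2, and after scaling it was 540 without female 2013 replicate 2. limma without trend gave 0 calls for 2013 minus 2012 and 2 for 2014 minus 2013. The F test over the 3 years called 627 features on the deposited scale and 31 after scaling. It called 25267 without male 2012 replicate 1, and 0 without male 2012 replicate 2. After scaling these counts were 799 and 0.

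The interaction asked whether the difference between the sexes itself differed among years. No feature was called in limma (0 on both scales and 0 without trend), with 807 features at an unadjusted p under 0.05 and a smallest adjusted p of 0.315. Among the 64 features that differed between the sexes, 0 passed with the p adjusted over these features alone, and the smallest adjusted p was 0.997. The cells of this test held as few as 2 libraries.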

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

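The tests of the 3 abundant features, of the table's detection filter and of mislabelled samples were chosen after the results they bear on had been seen.

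10 measurements in 52 groups of 4 to 10 libraries had a highest or lowest library far from the others, where chance gives about 1 group in 20. Most were in male 2012 replicate 1. The groups overlap, and so do some of the measures, so this 1 library is counted several times against that rate. Its share of TPM in the 3 most abundant features was 54.1%, against 2.70% to 16.7% in the other libraries of 2012, and it stood apart both among the 8 libraries of that year and among the 5 males. Its share in the top 10 features was 61.6%, against 9.49% to 23.8%, and stood apart in the same groups. It had the lowest median TPM of 2012, 1.37 against 3.39 to 4.72, and 973 features listed at 0, against 334 to 442 in the year and 334 to 378 among the males. Female 2013 replicate 2 listed 663 features at 0, against 295 to 463 in the other libraries of 2013. The listed features of female 2013 replicate 3 summed to 987069 TPM, against 993317 to 997966 in the other females. For TR5496|c0_g1, female 2012 replicate 2 was at 0.084 on the log2(TPM + 1) scale, against 0 to 0.029 in the other females.

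The first pattern is that 7812 features were called lower in 2014 than in 2012 on the deposited scale, with a median of -0.42. The room that the 3 abundant features take in the TPM total is argued against as its whole cause. With them left out and the rest rescaled, the median was -0.18, although 6 calls were left. It lay between -0.23 and -0.14 with each library also left out. The log2 share of these features as a covariate went further, to a median of -0.02 and 0 calls. A shift that goes with their share therefore stays open as the whole of the pattern. The number of lower calls rests on single libraries, since it fell to 0 without male 2012 replicate 5, while the median stayed between -0.56 and -0.34 in every such fit. Sampling date and year cannot be told apart, because with day of the year in the model the median was 0.11 and moved between -0.27 and 0.37 as single libraries were left out, and a difference between the seasons themselves stays open and untested.

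Other splits of the libraries bear on whether chance could give these counts. For 2014 minus 2012, 2 of 100 splits of the year labels, the real one included, gave as many calls as the real 7887, and the highest other gave 29451. The F test behaved alike, with 2 of 100 splits at 627 or more and a highest other of 21309. These shares are under 0.05, but the same single split exceeded the real labels in both tests, and both counts fell to 0 with 1 library left out (male 2012 replicate 5 for 2014 minus 2012, male 2012 replicate 2, among others, for the F test). Of the 100 splits that one had the largest difference in mean log2 median-ratio size factor between the libraries called 2014 and 2012, 0.75, and the real labels had the next in size, -0.53, so a shift in scale between libraries may lie behind both counts, although the split after these, at -0.47, gave 0 calls in both tests. After median-ratio scaling the real labels gave the most calls in both tests, 1 of 100 splits, with 241 against a highest other of 1 for 2014 minus 2012 and 31 against 2 for the F test. Without male 2012 replicate 2 these scaled counts of the real labels fell to 4 and 0. For the comparisons with 0 calls the splits decide nothing, since any split reaches a count of 0: 100 of 100 did for 2013 minus 2012 (highest other 7745, or 1 after scaling) and for 2014 minus 2013 (highest other 7897, or 9 after scaling). For the interaction, 99 of 99 splits reached it (highest other 28553, or 220 after scaling).

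The second pattern is that 61 of 64 features that differed between the sexes were higher in males. Chance is argued against for the number of calls, since 1 of 100 splits, the real one, gave as many as 64 calls (highest other 11). These splits moved the sex labels over all libraries and not within a year, and 8 others gave at least 1 call. After median-ratio scaling 1 of 100 gave as many as 78 (highest other 1). The splits were not used to test the direction of the calls. A mislabelled sample is argued against by placing each library on the male-higher features called without it, where 0 libraries lay on the wrong side: females had means between 0.122 and 0.368 and males between 2.08 and 3.86 on the log2(TPM + 1) scale. A feature absent from all but 2 males could not be listed. On the deposited scale this detection filter is argued against as the whole cause. There 34 male-higher features met a mirrored filter (above 0 in at least 2 females) against 3 female-higher ones (exact binomial p = 1.23e-07, or 1.40e-06 with each assembly cluster counted once). The test treats features as independent, which they are not. On this scale the median male minus female difference over all features was 0.08, so part of the excess may come from that shift. The floor on mean TPM and the filter at 1 TPM in 8 libraries, which females alone meet less easily, were not mirrored and stay open. After scaling the detection filter stays open too, with 33 against 18 (exact binomial p = 0.0489, or 0.144 by cluster). Among features above 0 in all 24 libraries the scaled counts were 10 against 17, where the direction turned (10 against 2 on the deposited scale). After scaling this choice kept 10 of 60 male-higher features and 17 of 18 female-higher ones. It removes any feature listed at 0 in a female, as many male-higher features are, so these counts cannot decide the direction. With scaling and sampling date as a block, 60 were higher and 7 lower in males, without the mirrored filter. That fit compares the sexes only on dates that hold both, with 15 libraries. Features on a male-specific chromosome are a biological explanation that was not tested.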

How the results depend on the processing

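Alternatives that leave out the 3 abundant features or the 2 libraries with the highest shares, use that share as a covariate, block by sampling date, or combine median-ratio scaling with another choice were chosen after seeing the data. No paired analysis was possible by replicate number because the labels do not pair animals across groups, but both sexes were sampled on 7 of 15 dates. The fits with a neutrophil or erythroid list and the gene list tests were not run, since the files do not pair features with symbols. What depth limits is not known. Except where named, the cause of a change was not tested.

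With each library left out the sex comparison gave 61 to 73 calls. With sampling date as a block in place of year it gave 65 calls, 60 higher and 5 lower in males. With scaling and the block it gave 67 calls, 60 higher and 7 lower, where scaling alone gave 18 lower. In a block fit only the 7 dates with both sexes, which hold 15 libraries, inform the sex difference. The smaller number of lower calls may therefore come from fewer libraries. It gave 42 calls with the stricter filter, which tests fewer features, and 97 with library weights. All 4 named sex features kept their direction and passed under every alternative in which they were tested.

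For 2014 minus 2012, 7887 calls became 241 with median-ratio scaling, 24 with quantile normalisation, 1523 with the stricter filter, 4442 with a pseudocount of 0.1, 31993 with library weights, 0 with day of the year, 17 in males only, 6 without the 3 features, 0 with their share as covariate and 24238 without the 2 libraries. With scaling combined they became 0 with day of the year, 1 in males only and 137 without the 2 libraries. Leaving out 1 library gave 0 to 31583. Of the libraries of 2012, it was 31583 without male replicate 1, 4 without 2, 3506 without 3, 3711 without 4 and 0 without 5, and 1077, 4801 and 2029 without female replicates 1, 2 and 3. Of 2014, it was 2183, 4504 and 729 without male replicates 1, 2 and 4 and 6 without female replicate 1. After scaling it was 4 to 1810. The 4 named year features kept their direction under every alternative and lost the threshold under 7 or 8 of 16. In the 24 fits with 1 library left out, TR26870|c0_g2 and TR34066|c0_g2 lost it in 3 each, TR40286|c0_g1 in 2 and TR18980|c1_g9 in 1.

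The F test among years, 627 calls, gave 31 with median-ratio scaling, 8 with quantile normalisation, 49 with the stricter filter, 48 with a pseudocount of 0.1, 27535 with library weights, 5557 with day of the year, 14 in males only, 16 without the 3 features, 0 with their share as covariate and 16075 without the 2 libraries. With scaling combined it gave 4 with day of the year, 1 in males only and 1 without the 2 libraries. Leaving out 1 library gave 0 to 25267, and 21 of 24 such fits moved it by over 1.5 times, all but those without male replicates 1 and 2 and female replicate 3 of 2013. After scaling it was 0 to 799.

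For 2014 minus 2013, 0 calls became 5 with quantile normalisation, 2 without trend, 5 with the stricter filter, 2 without sex, 11520 with library weights, 14205 with day of the year, 4 in males only, 106 without the 3 features, 22 without the 2 libraries and 2207 with scaling and day of the year. Leaving out 1 library gave 0 to 7100, with 7100 without male 2012 replicate 1, 3070 without female 2013 replicate 2 and at most 6 without any other. After scaling this was 0 to 540. For 2013 minus 2012, 0 calls became 32 with library weights, 4 with day of the year and 1 with scaling and day of the year, and 0 to 1 with 1 library left out. The interaction gave 1 call with library weights and 0 to 2 with 1 library left out.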

Other observations

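The tests in this part were chosen after the values they bear on had been seen.

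Some features that were lower in males lay in the same assembly cluster as a male-limited feature. After median-ratio scaling, 3 of the 18 female-higher features were cluster mates of the 54 male-limited features, where 0.00905 would be expected by chance (Fisher's exact test, p = 9.00e-08). On the deposited scale 0 of the 3 female-higher features were. With scaling and sampling date as a block, 7 features were called female-higher, and whether these include the cluster mates was not examined. Over all 23 cluster mates the median male minus female difference after scaling was -0.08, at percentile 1.54 of 10000 random lists of features matched on level, and on the deposited scale it was 0.005, at percentile 0.74, against 0.08 in the other features. In cluster TR18186 the mate was at 20.6 ± 3.01 scaled TPM in females and 14.4 ± 2.58 in males, and the male-limited feature was at 14.3 ± 3.02 in males (SD, n = 9 and 15). In TR41036 these values were 33.0 ± 6.14, 19.1 ± 3.87 and 3.99 ± 1.06, and in TR6166 they were 46.8 ± 14.8, 31.2 ± 4.08 and 19.8 ± 3.36.

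A hypothesis is that such a pair holds near-identical copies between which the reads of one total are split. The summed level of the male-limited features and the mates called female-higher would then be equal in both sexes. This summed level differed in 2 of the 3 clusters, in every fit with 1 library left out as well. It was higher in males by 8.01 scaled TPM in TR18186 and differed by -9.94 scaled TPM (male minus female) in TR41036 (each adjusted exact permutation p = 0.000268), and it was not shown to differ in TR6166, where it was higher in males by 4.28 scaled TPM (exact permutation p = 0.360). The result for TR6166 depends on 1 library, female 2014 replicate 1, at 83.4 scaled TPM against 33.7 to 52.2 in the other females: without it the difference was 8.86 (adjusted exact permutation p = 0.00607), and without female 2014 replicate 2 it was 2.65 (p = 0.611). TR18186 and TR41036 moved in opposite directions, so the sums of these features were not equal in all 3. This cannot decide whether reads were split, because the clusters were picked for mates called lower in males on the same scaled values. Any other members of a cluster were also left out of the sum. Sex-linked copies with levels of their own remain open and were not tested.

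After scaling, the median 2014 minus 2012 difference was 0.08 in features with an accession and -0.08 in those without one, and it also went with level. In the lowest of 10 equal bins of features by mean level the median was -0.10 with an accession and -0.17 without, and in the highest bin it was 0.17 and 0.18. Of the 181 higher calls 99 carried an accession, where 71.1 would be expected over all features (Fisher's exact test, p = 3.34e-05) but 120 from the level bins, so within level the link turned round (exact Mantel-Haenszel test, odds ratio 0.54, p = 0.000294). In the highest bin 52 of 3856 features with an accession and 16 of 728 without were called higher, and in the next bin 24 of 3445 and 22 of 1138. Of the 60 lower calls 20 carried an accession, with 23.6 expected over all features (Fisher's exact test, p = 0.359) and 22.7 from the level bins (exact Mantel-Haenszel test, p = 0.457), and these tests treat features as independent, which they are not. A value per library, the annotated minus unannotated difference averaged over these bins, was 0.030 ± 0.091 in 2014 and -0.011 ± 0.071 in 2012 (SD, n = 8 each), a difference of 0.041 with an exact permutation p = 0.335. With this spread between libraries a link to the year is not shown. The highest values were in female 2014 replicate 1 (0.201) and male 2012 replicate 1 (0.135), the libraries with the largest share of TPM in the 3 abundant features.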
